A study of Mus musculus with 7 samples.

How the data were processed

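RNA sequencing libraries were made from the soleus, a hindlimb muscle rich in slow-twitch fibres, of mice 60 days old. All animals carried mdx, the mutation that removes dystrophin from muscle and models Duchenne muscular dystrophy, and part of them also carried a floxed allele of Runx1, a transcription factor gene that is induced in denervated and damaged muscle. Per the labels, RNA was extracted from whole muscle with the 5PRIME PerfectPure tissue kit and libraries were prepared with the Illumina TruSeq protocol. The labels name neither a Cre driver nor the part of Runx1 between the loxP sites.

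The authors deposited 1 table of 29869 gene symbols for the 7 libraries. It holds raw read counts per gene, which the authors made with TopHat2 2.0.10 and HTSeq on the mm9 mouse genome, per the submitters' processing notes. A second block of columns holds each library's counts divided by a size factor, a signal on the scale of counts that the authors normalised before they deposited it. The ratio between both blocks was 1 constant per library, checked on the values. The table also gives the authors' log2 fold change with its standard error, and their p-value and adjusted p-value, per the file headers, which use the column names of DESeq2. The submitters' processing notes name DESeq2 1.6.3. The gene annotation, the strand setting, the treatment of reads that match more than 1 place and any filter are not given in the sources used here. Counts of genes with near-identical copies or overlapping transcripts are therefore uncertain. Genes were used under the symbols in the table. The gene table used for neighbours follows GRCm38.p6 and not mm9, so no coordinates are printed.

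Groups and replicate numbers were taken from the sample titles, which name a genotype, a number within the genotype and an animal. They give 4 libraries labelled mdx (animals 358, 361, 373 and 375) and 3 labelled mdx/Runx1f/f (animals 359, 363 and 374). The titles name 7 different animals, so the replicates were read as separate animals. Columns of the table are headed by animal number and were joined to the samples through the titles. Other labels conflict with the titles. The description field lists the same 7 animal numbers in ascending order over the samples, which ties most numbers to another sample. The design text of the series counts 3 mdx and 4 mdx/Runx1f/f muscles, the reverse of the titles. Since Runx1 itself was higher in the 3 libraries labelled mdx/Runx1f/f, the groups are called by their labels throughout. The total count per library was between 16218306 and 20847902. No pair of libraries agreed within sampling noise: over the tested genes the lowest chi-square of a pair was 15.9 per degree of freedom.

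The comparison was fitted with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter, and the quasi-likelihood test with group as the only term over all 7 libraries. P-values were adjusted by the Benjamini-Hochberg method over the 14033 genes that passed the filter, which hold 99.9% of all counts, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was the fold change divided by the root of its F statistic. Normalised read counts in the text are those of the authors, with the SD over libraries. For Runx1 a two-sided exact permutation test of its log2 CPM was added, which over 35 splits cannot give a p below 0.0286. The calling step was tested on simulated data with 14033 genes at the means and library sizes of this comparison and 200 genes changed 2-fold or 4-fold. It recovered 46.5% of genes changed 2-fold and 92.8% of genes changed 4-fold, and 3.55% of its calls were false. A further list of genes was given a smaller shift, and calls on those genes were not counted as false. The simulated genes were drawn independently, so these shares need not carry over to genes that move together.

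Before the data were examined, 36 gene lists were written for fibre types, regeneration, denervation, atrophy, proliferation, matrix, immune and stromal cell types, metabolism, stress, translation, the dystrophin complex, Runx factors with their cofactors, neighbours of Runx1 on its chromosome, and sex-linked genes. Of 773 list entries, 750 were in the table. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (counts scaled to the library size) with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. The rule for the genes named in the text was also fixed before: Runx1; the 12 largest positive and 12 largest negative log2 fold changes among called genes with a mean normalised count of at least 20 and groups that do not overlap, leaving out predicted genes without a name (symbols with Gm, Rik or LOC); up to 4 members of each list with the smallest p; and Runx2, Runx3, Cbfb, Dmd, Utrn, Myf5, Pax7, Myh3 and Myh8. Symbols made of a sequence accession were treated in the same way, a detail settled after the data were seen. A few genes that the rule or a list named are not reported here by themselves, but stay in every fit, count and list test. Genes outside the rule are said to be so where they appear.

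Alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, limma-voom, median-of-ratios size factors, no filter, a filter of 10 CPM in 3 libraries, the title number as a block, the animal number series as a covariate, groups read through the description field, 1 surrogate variable (sva 3.50.0), leaving out each library, and other thresholds. Fits on part of the animals were added after the data had been seen. Each of the 35 splits of the libraries into 4 and 3 was fitted as well.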

Results

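Transcripts were counted in whole soleus muscle of 7 mice aged 60 days, 4 labelled mdx and 3 labelled mdx/Runx1f/f. The comparison asks which transcripts differ in dystrophin-deficient muscle when the Runx1 alleles are floxed, as the series title names genes responsive to Runx1. The libraries labelled mdx held 16529110, 16807844, 17822361 and 18550109 counts in replicates 1 to 4, and those labelled mdx/Runx1f/f 17640547, 20847902 and 16218306 in replicates 1 to 3. Between 17460 and 18281 genes had a count in a library, and the 10 most abundant genes took 16.2% to 20.4% of the counts. The first principal component of log2 CPM, counts scaled to the library size, held 49.5% of the variance and placed the libraries labelled mdx between -51.2 and -3.44 and the others between 21.1 and 54.0. The second held 18.3% and did not part the groups. Xist was at 4 counts or fewer in each library, while the Y-linked genes Uty and Eif2s3y were expressed in all 7. These and Kdm5d were the 3 tested genes of the sex-linked list, with log2 fold changes between -0.25 and -0.22, and none was called by edgeR, DESeq2 or limma-voom or had an unadjusted p below 0.05.

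Runx1, the targeted gene, was 3.33-fold higher in the libraries labelled mdx/Runx1f/f, which goes against a loss of its transcript in that group. Its normalised read count was 919, 925 and 596 in these 3 libraries and 274, 273, 235 and 201 in the libraries labelled mdx, or 813 ± 188 (SD, n = 3) against 246 ± 34.5 (SD, n = 4). The log2 fold change was 1.74 (SE 0.18, adjusted p = 0.00795, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the two-sided exact permutation test gave p = 0.0286, the smallest value that 35 splits allow. Gene-level counts cover exons outside a deleted part of the gene, so they need not check the floxed allele. The description field sets animals 358 to 363 against animals 373 to 375, and that grouping gave 8 called genes against 975 by the titles. The authors' own fold changes follow the titles' grouping, while which of both groups carries which genotype stays open. Every direction given for these groups rests on the titles. Within animals 358 to 363 the log2 difference in Runx1 was 1.76 and within animals 373 to 375 it was 1.45. Fitted alone, the former series gave an adjusted p of 0.131 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over a range of 4.02e-13 to 0.131 across the alternatives that keep the titles.

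The other Runx genes were read in the same way. Runx3, at 9.86 ± 2.29 normalised counts (SD, n = 4) in the libraries labelled mdx and 44.2 ± 22.2 (SD, n = 3) in the others, rose with a log2 fold change of 2.16 (SE 0.37, edgeR adjusted p = 0.0207), on 7 to 13 raw counts per library labelled mdx. That call was lost without mdx replicate 2, mdx replicate 3 or mdx/Runx1f/f replicate 2 (edgeR adjusted p = 0.0522, 0.0666 and 0.0537). Runx2 had a log2 fold change of 1.10 (edgeR adjusted p = 0.0688) and Cbfb, the partner that all Runx proteins bind, 0.20 (edgeR adjusted p = 0.301), and neither was called. Of 15 tested Runx factors and cofactors, 3 rose and 0 fell, or 4 and 0 adjusted over the list alone. The risen genes were Runx1, Runx3 and the corepressor Tle3, at a log2 fold change of 0.78. The call of Tle3 was kept in 1 of the 7 fits that left out a library. The list was not called by camera (adjusted p = 0.308), its median was -0.02 and its mean 0.34, and fry gave an adjusted p of 0.0177. Of 33 tested genes that neighbour Runx1 on chromosome 16, none was called by edgeR, while 11 had an unadjusted p below 0.05, 6 were called by DESeq2 and 1 by limma-voom. The nearest to the threshold were Cbr3 (log2 fold change 1.00, edgeR adjusted p = 0.0510) and Dnajc28 (-0.56, edgeR adjusted p = 0.0582), and the list's median was 0.01 and its mean -0.01 (camera adjusted p = 0.412).

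**Figure D1:**
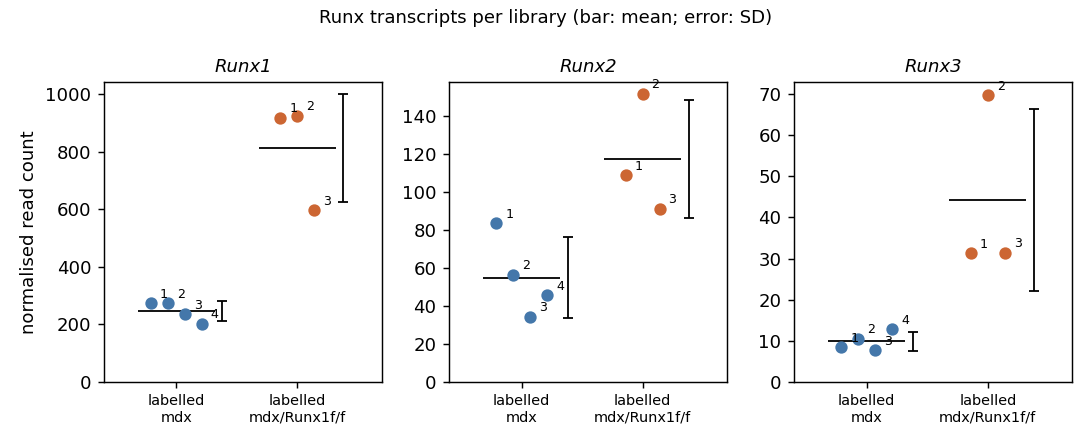
Normalised read counts of Runx1, Runx2 and Runx3 per library, by labelled group; points are libraries with their replicate number, bars are group means and error bars the SD. Runx1 was between 201 and 274 in the 4 libraries labelled mdx and between 596 and 925 in the 3 labelled mdx/Runx1f/f.

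Across the 14033 genes tested, 715 were higher and 260 lower in the libraries labelled mdx/Runx1f/f at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 456 were at least 2-fold higher and 42 at least 2-fold lower, and the median log2 fold change of all tested genes was -0.0016. The groups did not overlap in 973 of the 975 called genes and in 27.4% of all tested genes, against 5.71% by chance. On the same counts DESeq2 called 1472 higher and 872 lower genes, and edgeR called 240 and 80 with the title number as a block, 1246 and 582 with the animal number series as a covariate and 46 and 4 with 1 surrogate variable. The number of calls depended on single libraries: without mdx replicates 1, 2, 3 or 4 there were 641, 329, 219 and 290 higher and 162, 78, 44 and 94 lower genes, and without mdx/Runx1f/f replicates 1, 2 or 3 there were 499, 173 and 456 higher and 173, 17 and 209 lower genes. Fitted alone, animals 358 to 363 (2 against 2) gave 0 calls by edgeR and limma-voom, with 2643 genes at an unadjusted p below 0.05 and 688 calls by DESeq2, and animals 373 to 375 (2 against 1) gave 1308 higher and 421 lower genes. In the latter fit the spread comes from 2 libraries labelled mdx and the lone other library is assumed to vary like them, so its counts do not compare with the others.

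**Figure D2:**
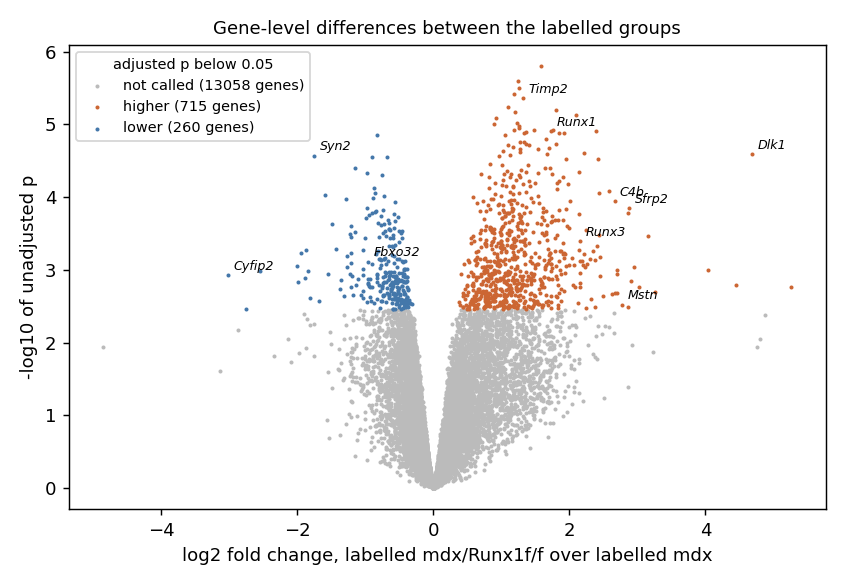
Log2 fold change of each of 14033 tested genes (labelled mdx/Runx1f/f over labelled mdx) against the negative log10 of its unadjusted p; each point is a gene and colours mark calls at an adjusted p below 0.05. There are 715 points called higher and 260 called lower.

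Among the called genes that met the naming rule, which leaves out predicted genes without a name, the largest rises were those of Dlk1, Cdkn2a and Ces1f. Dlk1, which encodes a transmembrane protein of the Notch ligand family that is abundant in fetal and regenerating muscle, was 25.8-fold higher, at 24.4 ± 10.6 normalised counts (SD, n = 4) in the libraries labelled mdx and 630.3 ± 427 (SD, n = 3) in the others (log2 fold change 4.69, SE 0.54, edgeR adjusted p = 0.00853). Cdkn2a, the locus of the cell cycle inhibitors p16 and p19Arf, was 8.90-fold higher (edgeR adjusted p = 0.0196). The desmosomal gene Dsp and the secreted Wnt-binding protein gene Sfrp2 had log2 fold changes of 2.91 and 2.88. Mstn, which encodes myostatin, an inhibitor of muscle growth, was 6.88-fold higher, at 31.1 ± 10.9 normalised counts (SD, n = 4) against 213 ± 215 (SD, n = 3), and its libraries labelled mdx/Runx1f/f stood at 459, 115 and 65.1. Il1rn, the interleukin 1 receptor antagonist gene, Aldh3a1, an aldehyde dehydrogenase gene, and the complement gene C4b had log2 fold changes of 2.70, 2.67 and 2.67. The carboxylesterase gene Ces1f, the paraoxonase gene Pon1 and the metallothionein gene Mt3 had 3.02, 2.86 and 2.62. Reads of C4b and Ces1f can be shared with close paralogs. Single libraries moved several of these values by over 1.5-fold. Without mdx/Runx1f/f replicate 1 the log2 fold changes of Dlk1, Cdkn2a, Mstn and Mt3 were 3.99, 2.42, 1.53 and 1.70, and without mdx/Runx1f/f replicate 3 those of Ces1f, Dsp and Pon1 were 1.94, 2.05 and 1.71. Without mdx replicate 1 that of Il1rn was 3.50, and without mdx replicate 2 that of Aldh3a1 was 3.45. Of these 11 genes, Dlk1, Sfrp2 and C4b kept the call whichever library was left out. Without mdx replicates 1, 2, 3 and 4 the call was lost for 5, 7, 8 and 7 of the 11, and without mdx/Runx1f/f replicates 1, 2 and 3 for 5, 6 and 3.

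Among the called genes that met the naming rule, Cyfip2, Slc15a5 and Hsbp1l1 fell furthest. Cyfip2, which encodes a subunit of the actin-regulating WAVE complex, was 8.07-fold lower, at 3967 ± 2337 normalised counts (SD, n = 4) in the libraries labelled mdx and 489 ± 231 (SD, n = 3) in the others (log2 fold change -3.01, SE 0.61, edgeR adjusted p = 0.0321). Slc15a5, a solute carrier gene, and Hsbp1l1 had log2 fold changes of -2.55 and -2.01, followed by Ctxn3 (-1.99), the glycosyltransferase gene Galnt5 (-1.95) and Rspo3 (-1.88), which encodes a secreted enhancer of Wnt signalling. The LIM-domain gene Fhl2, at 1088 ± 175 (SD, n = 4) against 298 ± 146 normalised counts (SD, n = 3), was 3.64-fold lower. Sh3rf2, the prothrombin gene F2, Ush1g and the guanine nucleotide exchange factor gene Fgd3 had log2 fold changes of -1.84, -1.81, -1.55 and -1.49. Syn2, which encodes the synaptic vesicle protein synapsin II, was 3.36-fold lower (SE 0.20 on the log2 scale, edgeR adjusted p = 0.00853) and was the gene of this group of 12 that kept its call whichever library was left out. Without mdx replicates 1, 2, 3 and 4 the call was lost for 3, 8, 10 and 3 of the 12, and without mdx/Runx1f/f replicates 1, 2 and 3 for 6, 10 and 5.

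By gene list, 18 of the 33 tested lists were called by camera, 14 higher and 4 lower. With an estimated correlation 0 lists were called and 3 had an unadjusted p below 0.05. Fry called 8: the lists of matrix, fibro-adipogenic progenitor, chemokine, T and NK cell, antigen presentation, Schwann cell, fatty acid oxidation and Runx genes. Calls also ended under other settings: those of T and NK cells and of mast cells with DESeq2, of T and NK cells and of tendon with the title number as a block, of tendon and of muscle transcription factors with 1 surrogate variable, and of muscle transcription factors and of early response genes with a filter of 10 CPM. Of the 78 called genes that the naming rule or a later choice singled out and that are reported, 24 kept their call whichever library was left out. Without mdx replicates 1, 2, 3 and 4 the call was lost for 19, 45, 50 and 38 of the 78, and without mdx/Runx1f/f replicates 1, 2 and 3 for 26, 45 and 22. The libraries labelled mdx/Runx1f/f differed among themselves in some fast-fibre transcripts. Myh4, a fast myosin heavy chain gene, stood at 246072, 53268 and 1293 normalised counts in their replicates 1 to 3. In the libraries labelled mdx it stood between 739 and 8982. With replicate 3 as the only library labelled mdx/Runx1f/f, a fit chosen after the data were seen that takes the lone library to vary like the other group, 94 genes were higher and 2 lower.

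Of 38 tested genes of the extracellular matrix, 24 rose and 0 fell, or 31 and 0 adjusted over the list alone, with a median log2 fold change of 1.26 (camera adjusted p = 4.41e-16, adjusted p = 0.328 with an estimated correlation). Timp2, an inhibitor of matrix metalloproteinases, rose from 2645 ± 321 (SD, n = 4) to 6575 ± 275 normalised counts (SD, n = 3), a log2 fold change of 1.32 (SE 0.12, edgeR adjusted p = 0.00795), and the collagen genes Col14a1 and Col5a1 had log2 fold changes of 1.93 and 1.40. Of 18 tested markers of fibro-adipogenic progenitors, the stromal cells that form connective tissue and fat in muscle, 13 rose and 0 fell, or 16 and 1 adjusted over the list alone (median 1.08, camera adjusted p = 2.91e-09, adjusted p = 0.325 with an estimated correlation). They included Dpt (1.27), Lum (1.29) and Pdgfra (1.08), the receptor gene that marks these cells. Of the 18 markers 5 also stand on another list, among them Lum on the matrix list, so these results are not independent. The 6 genes named here kept their call whichever library was left out. Of 14 tendon markers 1 rose and 0 fell, or 2 and 0 adjusted over the list alone (median 0.83, camera adjusted p = 0.0156, adjusted p = 0.630 with an estimated correlation). The risen gene was Comp, at 1.73, with Thbs4 at 1.53 (edgeR adjusted p = 0.0504), and the list was not called without mdx/Runx1f/f replicate 3 (camera adjusted p = 0.180). The macrophage list's mean log2 CPM was between 2.73 and 4.97 in the libraries labelled mdx and between 4.60 and 6.19 in the others. It did not follow the matrix list in each library. At a macrophage mean of 4.97, mdx replicate 1 had a matrix mean of 6.78. At 4.60, mdx/Runx1f/f replicate 3 had a matrix mean of 8.07. This pair of libraries came from different animal number series.

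**Figure D3:**
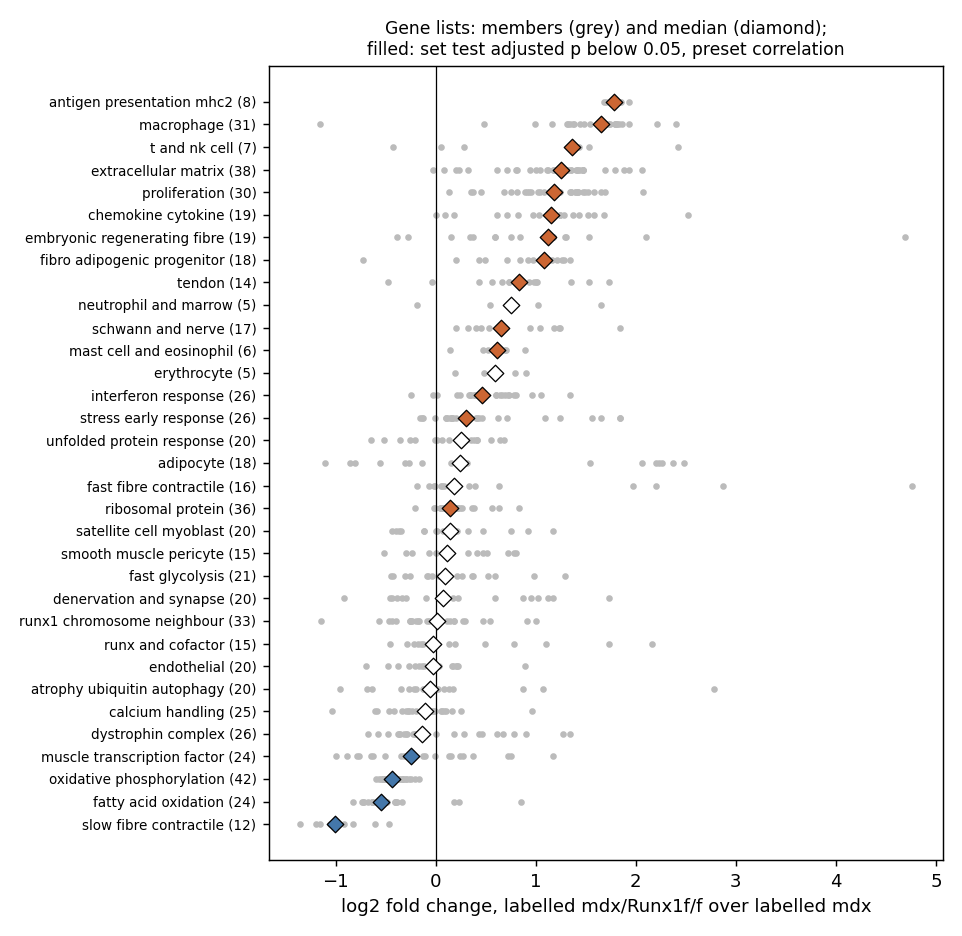
Log2 fold change (labelled mdx/Runx1f/f over labelled mdx) of each tested member (grey points) and median (diamonds) of the 33 tested lists, with the number of members in brackets. Filled diamonds are the 18 lists called by camera with the preset correlation, and medians run from -1.003 for slow-fibre genes to 1.79 for antigen presentation.

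Of 31 macrophage markers 7 rose and 0 fell, or 15 and 0 adjusted over the list alone (median 1.65, camera adjusted p = 2.91e-09, adjusted p = 0.630 with an estimated correlation). They included the fractalkine receptor gene Cx3cr1 (1.54), the integrin gene Itgax (2.41) and Ms4a7 (2.21), and the complement genes C1qa (1.75), C1qb (1.84) and C1qc (1.81), which were chosen for mention after their values were seen. The list's mean was 4.97 log2 CPM in mdx replicate 1, above the 4.60 of mdx/Runx1f/f replicate 3, which is of the other animal number series. Within animals 358 to 363 the list's mean was 4.97 and 4.05 in the libraries labelled mdx and 5.24 and 6.19 in the others. Within animals 373 to 375 it was 2.73 and 2.77 against 4.60. Of 8 genes of antigen presentation by class II molecules 7 rose, or 8 adjusted over the list alone (median 1.79, camera adjusted p = 3.68e-08, adjusted p = 0.270 with an estimated correlation). Cd74, the invariant chain gene, rose from 2853 ± 504 (SD, n = 4) to 9638 ± 1862 normalised counts (SD, n = 3), a log2 fold change of 1.77 (SE 0.18, edgeR adjusted p = 0.00795), with H2-Aa at 1.85 and H2-Ab1 at 1.81, members of a family of close paralogs. Of 19 chemokine and cytokine genes 3 rose, or 8 adjusted over the list alone (median 1.15, camera adjusted p = 3.68e-05, adjusted p = 0.328 with an estimated correlation): the macrophage growth factor gene Csf1 (1.03), the alarmin gene Il33 (1.58) and Cxcl14 (0.98). Cxcl14 also stands on the list of fibro-adipogenic progenitors. Of 7 T and NK cell markers 2 rose, Cd4 (2.42) and Klrk1 (1.53), or 3 adjusted over the list alone (median 1.36, camera adjusted p = 0.0290, adjusted p = 0.328 with an estimated correlation). Cd4 is also made by macrophages, and the mean of either gene in the libraries labelled mdx was below 10 normalised counts. The call of Klrk1 was lost whichever library was left out. That list was not called without mdx replicate 3, mdx replicate 4 or mdx/Runx1f/f replicate 2 (camera adjusted p = 0.0514, 0.165 and 0.0608).

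Further immune lists held few called genes. The list of mast cells and eosinophils had 0 of 6 members called by edgeR or limma-voom, 1 by DESeq2, 2 at an unadjusted p below 0.05 and 2 adjusted over the list alone (median 0.61, camera adjusted p = 0.0380, adjusted p = 0.630 with an estimated correlation). Mcpt4, a mast cell protease gene, had a log2 fold change of 0.70, and the list was not called without mdx replicate 1 or mdx/Runx1f/f replicates 2 or 3 (camera adjusted p = 0.110, 0.0848 and 0.137). Of 26 interferon response genes 0 were called by edgeR or limma-voom, 3 by DESeq2, 7 had an unadjusted p below 0.05 and 0 passed adjusted over the list alone (median 0.47, camera adjusted p = 0.00223, adjusted p = 0.630 with an estimated correlation), with Psmb9 at 1.05 and Irf9 at 0.48. Of 5 neutrophil and marrow markers 0 were called by edgeR or limma-voom, 1 by DESeq2, 1 had an unadjusted p below 0.05 and 1 was higher adjusted over the list alone (median 0.76, camera adjusted p = 0.412), with the metalloproteinase gene Mmp9 at 1.65. Of the 2 tested B cell markers, Cd22 rose with a log2 fold change of 1.83 and Cd79b stood at 0.37.

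Of 17 Schwann cell and nerve markers 4 rose and 0 fell, or 12 and 0 adjusted over the list alone (median 0.65, camera adjusted p = 1.63e-07, adjusted p = 0.254 with an estimated correlation): Egr2 (1.85), S100b (1.24), the peripheral myelin gene Pmp22 (0.65) and the myelin basic protein gene Mbp (0.62). Egr2 is also an early response gene and stood on that list too. Of 18 adipocyte markers 4 rose and 0 fell, or 6 and 3 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.380). The risen ones were the adiponectin gene Adipoq (2.26), the adipsin gene Cfd (2.20) and the lipid droplet genes Plin1 (2.23) and Cidec (2.38). Without mdx/Runx1f/f replicate 3 the log2 fold changes of Cfd, Plin1 and Cidec were 1.56, 1.47 and 1.72, and without mdx/Runx1f/f replicate 1 the list was called (camera adjusted p = 0.0283). Of 20 endothelial markers 1 rose, Vwf, with a log2 fold change of 0.89 (SE 0.16, edgeR adjusted p = 0.0243). The endothelial median was -0.03 and its mean -0.03, while camera's direction was up (adjusted p = 0.953). Of 15 markers of smooth muscle and pericytes 0 were called by edgeR or limma-voom, 3 by DESeq2, 7 had an unadjusted p below 0.05, and 2 higher and 1 lower passed adjusted over the list alone (median 0.12, camera adjusted p = 0.452), with Acta2 at 0.78 (edgeR adjusted p = 0.0518). Of 5 erythrocyte genes 0 were called by edgeR, DESeq2 or limma-voom or had an unadjusted p below 0.05 (median 0.59, camera adjusted p = 0.161), with Alas2 at 0.91. The erythrocyte list was called without mdx/Runx1f/f replicate 2 (camera adjusted p = 0.00619).

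All 12 slow-fibre contractile genes had a negative log2 fold change, with a median of -1.003 (camera adjusted p = 5.07e-05, adjusted p = 0.630 with an estimated correlation). None was called by edgeR or limma-voom or adjusted over the list alone, 8 had an unadjusted p below 0.05 and 4 were called by DESeq2. Myh7b, a slow myosin gene, had a log2 fold change of -1.20 (edgeR adjusted p = 0.0818), the slow light chain gene Myl3 -1.36 (edgeR adjusted p = 0.103) and the calsequestrin gene Casq2 -0.61. The list's mean was between 10.2 and 10.9 log2 CPM in the libraries labelled mdx and 8.64, 10.2 and 10.05 in the others, and the library at 8.64 was the one with the highest Myh4. Of 16 fast-fibre contractile genes 0 were called by edgeR or limma-voom, 1 by DESeq2 and 2 had an unadjusted p below 0.05, Myh4 (4.76, edgeR adjusted p = 0.0806) and the parvalbumin gene Pvalb (2.87, edgeR adjusted p = 0.151). Pvalb stood at 72886, 22823 and 669 normalised counts in mdx/Runx1f/f replicates 1 to 3. In the libraries labelled mdx it was between 2101 and 9599. The fast-fibre median was 0.18 (camera adjusted p = 0.622). Outside the naming rule, the fast myosin genes Myh2 and Myh1 stood at -0.18 and -0.07 (edgeR adjusted p = 0.819 and 0.947). In the libraries labelled mdx their means were 129103.5 and 86106 normalised counts, against 3754 for Myh4.

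Of 19 genes of embryonic or regenerating fibres 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (median 1.12, camera adjusted p = 0.00406, adjusted p = 0.630 with an estimated correlation). Beside Dlk1 these were Mustn1 (1.30), expressed in regenerating muscle, and the stretch-induced gene Ankrd1 (1.54). Myh3, the embryonic myosin heavy chain gene, had a log2 fold change of 1.17 (edgeR adjusted p = 0.161) and the neonatal gene Myh8 0.15 (edgeR adjusted p = 0.864). The list was not called without mdx/Runx1f/f replicate 1 (camera adjusted p = 0.0533). Of 20 satellite cell and myoblast genes 0 were called by edgeR or limma-voom, 4 by DESeq2 and 5 had an unadjusted p below 0.05 (median 0.14, camera adjusted p = 0.581). Pax7, which marks satellite cells, had a log2 fold change of 0.07 (edgeR adjusted p = 0.856), Myf5 -0.34, Vcam1 0.92 (edgeR adjusted p = 0.0600) and Notch3 0.47 (edgeR adjusted p = 0.0673). Of 24 muscle transcription factor genes 2 fell, also when adjusted over the list alone, among them Six4 (-0.78), and Mef2d stood at -0.32 (median -0.25, camera adjusted p = 0.0358, adjusted p = 0.630 with an estimated correlation). That list was not called without mdx replicate 3 or mdx/Runx1f/f replicate 2 (camera adjusted p = 0.0790 and 0.161). Of 20 genes of denervation and the synapse 1 was called, Runx1 itself, and Colq, which anchors acetylcholinesterase at the synapse, stood at -0.92 (edgeR adjusted p = 0.0693; median 0.07, camera adjusted p = 0.782).

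**Figure D4:**
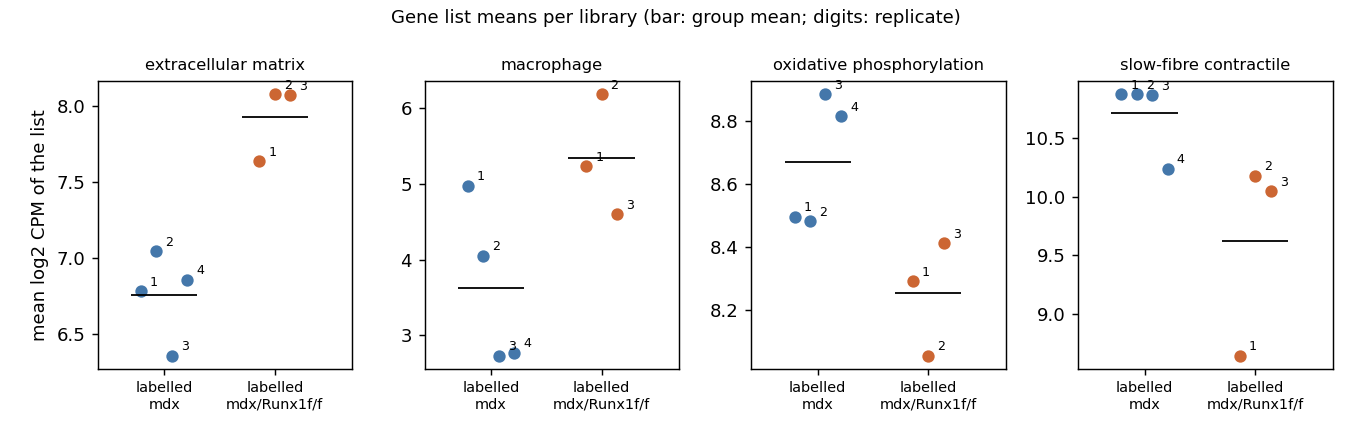
Mean log2 CPM of 4 gene lists per library, by labelled group; points are libraries with their replicate number and bars are group means. The matrix list is between 6.36 and 7.04 in the libraries labelled mdx and between 7.64 and 8.08 in the others. The ranges of the macrophage list overlap over all libraries but not within either animal number series.

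All 42 tested genes of oxidative phosphorylation had a negative log2 fold change, between -0.59 and -0.16 with a median of -0.43 (camera adjusted p = 6.59e-12, adjusted p = 0.630 with an estimated correlation). None was called over all genes by edgeR or limma-voom, 29 were lower adjusted over the list alone, 35 had an unadjusted p below 0.05 and 23 were called by DESeq2. Sdhc and Sdha, of complex II, had log2 fold changes of -0.51 and -0.59 (edgeR adjusted p = 0.0584 and 0.0647) and Cox7b -0.48. The list's mean was between 8.48 and 8.89 log2 CPM in the libraries labelled mdx and between 8.05 and 8.41 in the others, and the macrophage and matrix lists moved the opposite way in the same libraries. Of 24 genes of fatty acid oxidation 4 fell and 0 rose, or 19 and 0 adjusted over the list alone (median -0.55, camera adjusted p = 1.06e-07, adjusted p = 0.465 with an estimated correlation). Cpt1b, the muscle carnitine palmitoyltransferase that admits fatty acids to mitochondria, fell from 12143 ± 1550 (SD, n = 4) to 7376 ± 110 normalised counts (SD, n = 3), a log2 fold change of -0.71 (SE 0.13, edgeR adjusted p = 0.0265), with Cpt2 at -0.59, the acyl-CoA dehydrogenase gene Acadm at -0.74 and Echs1 at -0.57. Each of these 4 calls was lost in 5 or 6 of the 7 fits that left out a library, mdx/Runx1f/f replicate 2 among them. The only mitochondrially encoded gene of the table that was listed and tested, mt-Nd4, had a log2 fold change of -0.15. Of 21 glycolysis genes 0 were called by edgeR or limma-voom, 1 by DESeq2 and 2 had an unadjusted p below 0.05, Slc2a4 (-0.45) and Hk2 (-0.31). The glycolysis median was 0.09 and its mean 0.16, while camera's direction was down (adjusted p = 0.782), and without mdx/Runx1f/f replicate 1 the list was called lower (camera adjusted p = 0.00365).

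Of 30 proliferation genes all had a positive log2 fold change with a median of 1.19 (camera adjusted p = 2.81e-05, adjusted p = 0.630 with an estimated correlation). With 1 surrogate variable the list was not called and camera's direction turned to down (adjusted p = 0.669). In the main fit the macrophage list was higher too, with a median of 1.65. None of the 30 proliferation genes was called by edgeR or limma-voom or adjusted over the list alone. Among them 13 had an unadjusted p below 0.05 and 6 were called by DESeq2. The cyclin genes Ccnd1 and Ccnd2 stood at 0.93 and 0.75 and the mitotic kinase gene Plk1 at 1.70. Of 26 stress and early response genes 3 rose, or 5 adjusted over the list alone, namely Egr2 (1.85), Socs3 (1.24), an inhibitor of cytokine signalling, and Nr4a3 (1.84) (median 0.31, camera adjusted p = 0.0281, adjusted p = 0.630 with an estimated correlation). The calls of Socs3 and Nr4a3 were each kept in 1 of the 7 fits that left out a library, and that of Egr2 in all 7. The stress list was not called without mdx replicate 1 or mdx/Runx1f/f replicate 3 (camera adjusted p = 0.135 and 0.364). Of 36 ribosomal protein genes 0 were called by edgeR, DESeq2 or limma-voom and 4 had an unadjusted p below 0.05 (median 0.15, camera adjusted p = 0.0153, adjusted p = 0.682 with an estimated correlation), with Rplp1 at 0.36 and Rps16 at 0.38. These genes have many processed copies, and the list was not called without mdx replicate 4 or mdx/Runx1f/f replicate 2 (camera adjusted p = 0.161 and 0.232). It was not called either by DESeq2 or with the title number as a block, and with 1 surrogate variable its direction turned to down (camera adjusted p = 0.885). Of 20 genes of the unfolded protein response 0 were called by edgeR or limma-voom, 2 by DESeq2 and 7 had an unadjusted p below 0.05 (median 0.26, camera adjusted p = 0.213), with Dnajc3 at 0.42 and Ddit3 at -0.51. Of 20 genes of atrophy, the ubiquitin ligases and autophagy, Mstn rose and Fbxo32, the atrogin-1 ubiquitin ligase gene, fell with a log2 fold change of -0.96 (SE 0.18, edgeR adjusted p = 0.0273). Adjusted over the list alone 1 rose and 3 fell, and the median was -0.06, the mean 0.07 and camera's direction down (adjusted p = 0.270).

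Of 26 genes of the dystrophin complex and its partners 2 rose and 1 fell, or 6 and 5 adjusted over the list alone. The biglycan gene Bgn (1.27) and the syntrophin gene Sntb2 (0.61) rose. The call of Sntb2 was lost whichever library was left out and that of Bgn without mdx replicate 4 or mdx/Runx1f/f replicate 2 (edgeR adjusted p = 0.0574 and 0.0650). The list's median was -0.14, its mean 0.08 and camera's direction down (adjusted p = 0.622). Dmd itself, whose mutation is shared by both groups, had a log2 fold change of -0.36 (edgeR adjusted p = 0.113) and its homologue Utrn 0.28 (edgeR adjusted p = 0.238). Of 25 calcium handling genes 1 fell, Stac3, an adaptor needed for excitation-contraction coupling, with a log2 fold change of -0.58 (edgeR adjusted p = 0.0314). Stim1 stood at -0.41, and the calcium list was not called (median -0.11, camera adjusted p = 0.0775) except without mdx replicate 1, mdx replicate 2 or mdx/Runx1f/f replicate 1 (camera adjusted p = 0.0487, 0.0447 and 0.00365).

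The authors' deposited table gave 1666 higher and 1172 lower genes at an adjusted p below 0.05 among 14935 genes with an adjusted p. Across genes, which are not independent replicates, its fold changes correlated at 0.965 with the difference between the groups of the titles, and at most at 0.919 with any other of the 91 splits compared, which sets its positive sign to the libraries labelled mdx/Runx1f/f. All 975 genes called here were also called in the authors' deposited table with the same sign, and the sign was shared by 99.3% of the 14033 genes tested in both. Runx1 had a log2 fold change of 1.604 (SE 0.20, adjusted p = 2.61e-13) in the authors' deposited table.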

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

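The tests on exchanged titles, on splits within the animal number series, on the share of muscle fibres and on the neighbours of Runx1 were chosen only after the result was seen. Those on macrophage content and on fast muscle were also set up with the Runx1 difference and the Myh4 counts in view. When the 7 libraries were split into 4 and 3 in all 35 possible ways, only the split by title, 1 of the 35, gave as many as 975 called genes. The highest other split gave 8. The share of 1 in 35, or 0.0286, is the smallest that these splits allow. Every other split mixes the labelled groups, which widens the spread within its sides and lowers its calls, so the low counts do not exclude chance. The split that gave 8 set mdx replicates 3 and 4 with mdx/Runx1f/f replicate 3, which are the animals 373 to 375. The description field gives this same grouping. Of the 18 splits that keep the number of libraries of each animal number series per group, the highest other than the titles gave 1, and they are too few for a share under 0.05.

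Runx1 was higher in the libraries labelled mdx/Runx1f/f, as were 7 of 31 markers of macrophages, which express Runx1. With the mean of the macrophage list in the model, the group difference in Runx1 remained 1.34 log2 units (SE 0.22). Without that mean it was 1.71 (SE 0.21). The macrophage mean itself differed between the groups and is an imprecise measure of cell content. A model of 7 libraries therefore cannot exclude macrophage content as the cause. All 31 macrophage markers were detected in every library labelled mdx, where Lyz2, Ctss and Mpeg1 were the most abundant at mean normalised counts of 3333, 1219 and 1121, and 1 marker also stands on another list. Exchanged titles remain open: the ratio of group means was 3.31, the direction an exchange would give, and the design text counts the groups the other way round, but gene-level counts cannot tell transcripts of a floxed allele from intact ones. A strain segment carried with the floxed allele may also contribute and cannot be told apart, since 33.3% of the 33 tested neighbours had an unadjusted p below 0.05, as against 29.5% of all tested genes, with 0 called by edgeR, 6 by DESeq2 and 1 by limma-voom; a response of the floxed genotype itself stays open as the biological explanation and was not tested.

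All 12 slow-fibre genes had negative fold changes, with 0 called by edgeR or limma-voom, 4 by DESeq2 and 8 at an unadjusted p below 0.05 (camera adjusted p = 5.07e-05, adjusted p = 0.630 with an estimated correlation, fry adjusted p = 0.138), and 260 genes of any kind were called lower in the libraries labelled mdx/Runx1f/f, where Myh4 was far above the range of the libraries labelled mdx in replicates 1 and 2 and within it in replicate 3. Fast muscle carried over at dissection may explain part of this. Over the 208 genes called lower without replicate 3, the median log2 difference of replicate 3 was -0.42 and that of replicates 1 and 2 was -0.76, a ratio of 0.546 (95% bootstrap interval 0.474 to 0.585, 2000 draws over genes). For the slow-fibre list these medians were -0.65 and -1.40. The ratio leaves a difference in the library with little Myh4, but it does not decide, because its interval spans the bound set for it and the genes were selected on the same libraries labelled mdx, and the genotype stays open as an untested biological explanation.

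Of the matrix list 24 of 38 genes and of the macrophage list 7 of 31 were called higher in the libraries labelled mdx/Runx1f/f, and neither list was called with an estimated correlation (adjusted p = 0.328 and 0.630). A lower share of muscle fibres would raise markers of every other cell type alike if those cells kept their proportions. The endothelial list did not rise alike, with a median of -0.027 (95% bootstrap interval -0.15 to 0.09). That is below 0.628, which is the matrix median of 1.26 divided by 2. The interval comes from draws over genes of the same libraries, so it leaves out the spread between animals. It therefore does not decide whether a lower fibre share caused the matrix rise. The smooth muscle and pericyte list had a median of 0.12 (0.00284 to 0.52), while the Schwann cell list at 0.65 and the tendon list at 0.83 lay above 0.628, so markers of other cell types moved apart and a lower fibre share may still account for part of the rise. A change in the stromal and immune cells themselves stays open, and the genotype was not tested apart from the labels.

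In the 4 libraries labelled mdx, 12 of 166 values or list means had one library far from the other 3, by Dixon's test at the 95% level, which chance gives in about 1 of 20 groups. In mdx replicate 1, the normalised count was 16.9 for Il1rn (3.31 to 5.22 in the other libraries), 209 for Adipoq (90.8 to 107), 9949 for Hk2 (8145 to 8348) and 1054 for Eif2s3y (1364 to 1408), and the adipocyte list had a mean of 5.21 log2 CPM (4.65 to 4.73). In mdx replicate 2, Aldh3a1 stood at 16.7 (3.17 to 4.94). In mdx replicate 3, Lum stood at 1242 (1483 to 1498), the tendon list at 3.04 (4.13 to 4.34) and the calcium handling list at 8.36 (8.12 to 8.16). In mdx replicate 4, the slow-fibre list stood at 10.24 (10.87 to 10.88), the Schwann cell list at 2.57 (2.37 to 2.39) and the list of Runx factors and cofactors at 4.05 (3.93 to 3.95). No explanation was tested for these values.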

How the results depend on the processing

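The fits on part of the animals were chosen only after the result was seen; the other alternatives were not. Every call on a gene kept its sign under each alternative that keeps the titles and uses all 7 libraries or leaves out 1. Of the 975 called genes, 974 were also called by the DESeq2 Wald test, 911 by limma-voom, 959 with median-of-ratios size factors, 880 without a filter and 641 with the filter of 10 CPM, under which fewer genes were tested. The counts of higher and lower genes were 1472 and 872 with DESeq2, 240 and 80 with the title number as a block (250 of the 975 also called), 1246 and 582 with the animal number series as covariate (972 of the 975), and 46 and 4 with 1 surrogate variable (46 of the 975); the cause was not tested. At an adjusted p threshold of 0.1 they were 1592 and 935, and at 0.01 they were 44 and 4, by construction. Leaving out 1 library gave 173 (without mdx/Runx1f/f replicate 2) to 641 higher genes and 17 (the same library) to 209 lower genes. As totals, which need not hold the same lists or directions as the 18 reported, 0 lists were called with an estimated correlation between genes (3 at an unadjusted p below 0.05), 8 with fry (among them the Runx list, not called by camera), 12 with the description field, 14 to 19 under the other alternatives of the fit and 15 to 20 without 1 library. Runx1 had a log2 fold change of 1.63 to 1.91 without 1 library, 1.63 with the block (adjusted p = 0.0467) and 1.42 with 1 surrogate variable (adjusted p = 0.0439), within a range of 4.02e-13 to 0.131 over the alternatives that keep the titles. Fitted alone, animals 358 to 363 gave 0 higher and 0 lower genes by edgeR (2643 at an unadjusted p below 0.05, 688 by DESeq2, 0 by limma-voom) and Runx1 at 1.77 (adjusted p = 0.131), and animals 373 to 375, 2 libraries against a lone one, gave 1308 and 421 genes on the spread of a pair of libraries. With mdx/Runx1f/f replicate 3, whose Myh4 lay in the mdx range, as the only library of its group, 94 and 2 genes were called and Runx1 stood at 1.29 (adjusted p = 0.0577). In both fits with a lone library it is assumed to vary like the other group, so their counts do not compare with those of the other fits. At the depth and numbers of these libraries, 46.5% of simulated 2-fold changes were recovered. Neither depth nor the number of libraries was varied, so this share does not show what sets the limit. Groups read through the description field set animals 373 to 375 against animals 358 to 363. That reading therefore compares the animal number series, and each of its sides mixes both labels of the titles. Under it 5 genes were higher and 3 lower, 829 of the 975 changed sign, and Runx1 reversed to -0.80 (edgeR adjusted p = 0.615). Log2 fold changes under that reading reversed to Dlk1 -0.97, Cdkn2a -1.12, Sfrp2 -0.74, Mstn -1.91, Il1rn -1.56, Aldh3a1 -0.20, Mt3 -1.50, Timp2 -0.27, Col14a1 -0.087, Col5a1 -0.24, Dpt -0.11, Lum -0.13, Pdgfra -0.32, Cx3cr1 -0.63, Itgax -1.14 and Ms4a7 -1.26. Further genes reversed to Csf1 -0.39, Il33 -0.74, Cxcl14 -0.53, Cd22 -1.16, Cd74 -0.11, H2-Aa -0.11, H2-Ab1 -0.050, Vwf -0.039, S100b -0.056, Mbp -0.16, Comp -0.31, Bgn -0.40, Sntb2 -0.28, Runx3 -0.81, Tle3 -0.45 and Socs3 -0.70. Others that became negative were Nr4a3 -0.040, C3 -0.25, C2 -0.055, Cfb -0.50, Meg3 -0.46, Rian -0.27, Mirg -0.27, Sfrp1 -0.57, Sfrp4 -0.47 and Sfrp5 -0.073. Genes lower by title became Slc15a5 1.26, Hsbp1l1 0.48, Galnt5 0.0012, Rspo3 0.49, Fhl2 0.26, Syn2 0.54, Ush1g 0.46, Fgd3 0.73, Fbxo32 0.21, Cpt1b 0.32, Cpt2 0.39, Acadm 0.49, Echs1 0.29, Stac3 0.24, Six4 0.41 and Nnt 0.21. Under the description field these lists changed to lower, with camera adjusted p: proliferation 2.14e-06, matrix 0.293, fibro-adipogenic progenitor 0.346, macrophage 7.25e-14, chemokine 0.0397, T and NK cell 0.292, neutrophil 0.00238, antigen presentation 0.252, interferon 0.483, tendon 0.528 and ribosomal protein 0.000121. These changed to higher: slow-fibre 0.402, oxidative phosphorylation 7.25e-14, fatty acid oxidation 8.62e-05, calcium handling 0.0271 and muscle transcription factor 0.0205. With 1 surrogate variable the proliferation list (camera adjusted p = 0.668) and the ribosomal protein list (0.885) changed to lower; the cause was not tested. The pseudocount on the log scale was not varied, since counts were tested.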

Other observations

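The gene groups and single genes given here were chosen only after the result was seen, and no set test was run on them. Of 19 tested genes of the complement system and its regulators 12 rose and 0 fell in the libraries labelled mdx/Runx1f/f, 7 did not pass, and the median log2 fold change was 1.46. The risen genes include the recognition subunits C1qa, C1qb and C1qc, which macrophages make and which also stand on the macrophage list, the proteases C1ra (1.31), C1s (1.12) and C2 (2.01), the central components C3 (2.44) and C4b (2.67), the alternative pathway genes Cfb (1.96) and Cfd (2.20), and the regulator Serping1 (1.24). C3 rose from 583 ± 297 (SD, n = 4) to 3135 ± 939 normalised counts (SD, n = 3) (edgeR adjusted p = 0.0192), and its call, like those of C2, Cfb and C4b, was kept whichever library was left out. Among the genes that did not pass, Masp1 stood at -0.75 (edgeR adjusted p = 0.0756) and Cd59a at -0.46 (edgeR adjusted p = 0.0743).

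A pair of small groups was formed around Sfrp2, which encodes a secreted inhibitor of Wnt signalling, and around Dlk1, which lies in an imprinted region of chromosome 12, after both had been seen to rise. Of 5 secreted frizzled-related genes 4 rose, Sfrp1 (2.14), Sfrp2 (2.88), Sfrp4 (2.43) and Sfrp5 (1.28), each in all 7 fits that left out a library, and Frzb stood at -0.38 (edgeR adjusted p = 0.400). Of 6 genes of the imprinted region 4 rose: the paternally expressed Dlk1 and the maternally expressed noncoding Meg3 (2.15), Rian (2.35) and Mirg (2.50), while Rtl1 stood at 2.40 (edgeR adjusted p = 0.0696) and Dio3 at 1.11 (edgeR adjusted p = 0.248). Without mdx/Runx1f/f replicate 1 the log2 fold changes of Dlk1 and Mirg were 3.99 and 1.88. The call of Dlk1 was kept in all 7 fits that left out a library, those of Meg3 and Rian in 5 each and that of Mirg in 1. Meg3 was at 1894 ± 669 (SD, n = 4) and 8351 ± 4603 normalised counts (SD, n = 3). The strand setting of the counts is not given, so reads of overlapping transcripts in this region are not assigned with certainty.

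A pair of single genes stood out. Nnt, which encodes a mitochondrial transhydrogenase, fell from 14101 ± 1463 (SD, n = 4) to 6851 ± 2207 normalised counts (SD, n = 3), a log2 fold change of -1.04 (edgeR adjusted p = 0.0387), a call kept in 2 of the 7 fits that left out a library. Gm4841, of a family of interferon-induced GTPase genes with close paralogs, stood at 445, 49.3 and 2191 normalised counts in the libraries labelled mdx/Runx1f/f and between 8.45 and 36.6 in those labelled mdx, a log2 fold change of 5.26 (edgeR adjusted p = 0.0363) whose call was kept in 1 of the 7 fits. Without mdx/Runx1f/f replicate 3 it was 3.402. No explanation was tested for these values.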
